A study of Arabidopsis thaliana with 24 samples.

How the data were processed

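The series measured RNA of Arabidopsis thaliana Col-0 on 24 Affymetrix ATH1 arrays, with shoots and roots sampled at 6 times after bleomycin and mitomycin were added and 2 arrays per tissue and time. The labels do not say that the 2 arrays of a group came from separate cultures or plants, so the p-values measure only the spread between these samples, which may be technical. The deposited values were linear signal intensities made with MAS5 per the submitters' processing notes, 22810 probe sets per array. Each array had been scaled to a trimmed mean of 100, with the lowest and highest 2% of probe sets left out. The MAS5 version and settings were not given in the sources used here. Detection calls and raw probe intensities were not used here, so a dim probe set could not be told from background, and no depth applies. The 24 arrays are what limits precision. Untreated plants were not analysed here.

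The 64 probe sets of the array's own controls were left out, which left 22746. Signals were turned to log2(signal + 16) and fitted in R 4.3.3 with limma 3.58.1, with a mean for each of the 12 groups, empirical Bayes variances with an intensity trend (12 residual and 4.91 prior degrees of freedom) and p-values adjusted by the Benjamini and Hochberg method within each comparison. An adjusted p below 0.05 was taken as a change. The smallest fold called at 24 h was 1.15 in shoots and 1.16 in roots. Comparisons were of each time from 1 to 24 h with 0.5 h within each tissue, of the 24 h change between tissues (roots minus shoots), of shoots with roots over all times, and of any change over time. Standard errors are those of limma. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

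Probe sets were named from the array's annotation table. Of them 13513 carried 1 gene, 503 several, and 8730 were not listed there and are unnamed here, not without a gene. Names were matched to loci of the TAIR10.1 annotation for 13436 probe sets of 13355 genes, of which 1557 had a symbol other than the locus and 147 had several probe sets. A gene was represented by its probe set with the highest mean. Some probe sets, such as those of AT1G59265 and AT2G15220, carry a suffix by which the maker marks probes shared by several transcripts.

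The comparisons, the rule for naming genes, 22 gene lists and most alternatives were chosen before the data were examined. Genes were named by this rule: the 12 largest rises and 12 largest falls at 24 h in each tissue among single-gene probe sets that passed and whose 2 later arrays lay on the same side of both earlier ones; the 8 largest differences between tissues each way; the passing members of the DNA damage response list and, for the other lists, the 2 to 4 passing members with the largest change; and the 3 largest of each tissue marker list. Features outside this rule are named as chosen after their values were seen, and members that did not pass are given as values. The 22 lists held 360 genes, of which 55 had a named probe set. In 10 lists at least 3 were measured, in 10 lists 1 or 2, and in 2 lists, jasmonate and salicylate and defence, none, so no result exists for these 2. Because of this, 18 further lists were written before any expression change was computed, except that the symbol pattern for glutathione transferases was corrected after a first fit. The annotation and array summaries had been seen by then, so these lists are counted below as chosen after the data were seen. The naming rule was also applied to them, and their tests were adjusted as a separate family. The damage-induced loci were listed from recall of published studies.

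Lists with at least 3 measured genes were tested with camera in limma at a preset correlation of 0.01 between genes, which compares the list with all other genes. They were tested again with a correlation estimated from the data and with fry, which tests whether a list's genes move on balance one way and makes no comparison with other genes. Counts of list members are given over all genes and, for the lists fixed in advance, also adjusted over the list alone.

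Alternatives were pseudocounts of 1 and 64, quantile normalization over all arrays and within each tissue, median centring, removal of the dimmest 30% or 50% of probe sets, variances without trend, each tissue fitted alone, the replicate number as a block, 1 h or the mean of 0.5 h and 1 h as the baseline, the median over a gene's probe sets, and each array left out in turn, where the lone array of a group is assumed to vary like other groups. Leaving out both shoot arrays nearest to the roots, the 18 further lists and a screen of 43 symbol families with at least 6 genes were added after the data had been seen. The fit was tested on simulated data with 50 changed probe sets per fold size. In shoots at 24 h it recovered 56% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, with 9 false calls, in roots 44%, 96% and 100% with 8, and for the difference 8%, 74% and 96% with 14. A simulated list of 15 genes raised by 0.6 was called, and none of the others was. The simulated noise was independent between genes and between arrays. These runs therefore do not show how often lists or probe sets are called falsely where genes are correlated. Far fewer probe sets were changed in them than were called in the data at 24 h, 4315 in shoots and 2975 in roots. The adjusted threshold depends on that number, so the recovery and the false calls do not carry over to the data.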

Results

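Transcript levels were measured on Affymetrix ATH1 arrays in shoots and roots of Arabidopsis thaliana Col-0 plants, 16 days old, that had been given bleomycin, which breaks DNA strands, together with mitomycin, which crosslinks them. Per the labels, the drugs were used at 1.5 µg/ml and 22 µg/ml, and the rafts that carried the plants were lifted while they were stirred into the medium. Samples were taken after 0.5, 1, 3, 6, 12 and 24 h, which gave 12 groups of 2 arrays, 24 arrays in all. Treatment began 3 h into a 16 h light period, so these samples fell 3.5, 4, 6, 9, 15 and 3 h after lights on. Untreated plants were not analysed here, and each time was therefore set against 0.5 h in the same tissue. Of these comparisons, that of 24 h is nearly matched for the hour of day, whereas at 1 to 12 h the length of treatment and the hour of day changed together. The median signal per array lay between 35.96 and 39.9 in shoots and between 45.25 and 47.8 in roots, and the log2 signals of the 2 arrays of a group correlated across probe sets with r between 0.984 and 0.992 in shoots and between 0.987 and 0.993 in roots. The first array at 12 h and the second at 24 h in shoots resembled the root arrays more (mean r 0.714 and 0.711) than the other 10 shoot arrays did (0.678 to 0.692). The number of arrays limits the precision of every value below, each of which compares groups of 2 arrays unless stated. Changes are on the log2(signal + 16) scale with standard errors, and adjusted p-values are from limma.

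Shoots and roots were first compared over all times, 12 arrays each, as a check of the tissue labels. Transcripts of leaf photosynthesis were far higher in shoots, among them LHCB4.2 (AT3G08940) and LHCB4.1 (AT5G01530), light-harvesting antenna proteins, by 6.01 ± 0.09 and 4.91 ± 0.07, and RCA (AT2G39730), Rubisco activase, by 5.32 ± 0.08. The root-enriched β-glucosidase PYK10 (AT3G09260) was lower in shoots, with a difference of -2.51 ± 0.06, as were the root hair expansins EXPA7 (AT1G12560) at -1.08 ± 0.08 and EXPA18 (AT1G62980) at -0.99 ± 0.08. All 3 measured photosynthesis markers were higher in shoots and all 3 root markers lower, with the same counts adjusted over the list alone. As a set, the photosynthesis markers passed (adjusted p = 0.00189, adjusted p = 0.237 with an estimated correlation) and the root markers did not (adjusted p = 0.122). In longer lists, all 16 photosynthesis genes and all 69 genes of the plastid genome were higher in shoots (adjusted p = 1.77e-15 and 2.87e-33, adjusted p = 0.0956 for both with an estimated correlation). Of 22746 probe sets, 17466 differed, 6284 higher and 11182 lower in shoots. That split, 36% higher, moved with the scaling. It was 47.4% after quantile normalization over all arrays (8472 of 17856) and 56.6% after each array was centred on its median (10730 of 18961), settings that raised the median difference of all probe sets by 0.108 and 0.205.

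Rises and falls were ranked by the naming rule among probe sets with 1 gene. The 8730 unlisted probe sets and the 503 with several genes were therefore not ranked in either tissue. In shoots, 24 h against 0.5 h of treatment, the strongest ranked rise was that of AT5G60250, 9.63-fold (3.27 ± 0.17, adjusted p = 2.26e-09). AT4G22960 rose by 2.51 ± 0.19, AT2G45460 by 2.49 ± 0.19 and AT3G45730 by 2.29 ± 0.18. All 4 are on the list of damage-induced loci, which was written from recall of published studies, some of which may have used these arrays. The strongest ranked fall was that of AT1G02660, 10.7-fold (-3.42 ± 0.18, adjusted p = 2.26e-09). AKINBETA1 (AT5G21170), a regulatory subunit of the energy-sensing kinase SnRK1, changed by -2.23 ± 0.15. WES1 (AT4G27260), an enzyme that conjugates auxin to amino acids, changed by -1.59 ± 0.18 and the transcription factor gene WRKY22 (AT4G01250) by -1.68 ± 0.17.

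In all, 4315 probe sets passed in shoots at 24 h, 2014 higher and 2301 lower. Centring each array on its median turned the split from 46.7% to 57.2% higher (2357 higher and 1763 lower of 4120), and without both shoot arrays that lay nearest to the roots 3518 passed. The other 8 of the 12 largest rises were those of AT2G27420 (3.13 ± 0.16), AT2G15020 (3.01 ± 0.16), TBL26 (AT4G01080, 2.60 ± 0.16), AT1G20120 (2.57 ± 0.17), AT1G76960 (2.42 ± 0.22), AT1G47400 (2.37 ± 0.56), AT1G65500 (2.34 ± 0.29) and AT5G42760 (2.30 ± 0.16). AT1G47400 rested on 1 array, with a rise of 3.41 without the first array at 24 h and a value of 1.34, no longer past the threshold, without the second. The other 11 of the 12 largest falls were those of EXLA1 (AT3G45970, -2.95 ± 0.36), an expansin-like gene, AT2G15960 (-2.85 ± 0.30), AT2G30600 (-2.77 ± 0.27), AT3G15450 (-2.61 ± 0.18), AT3G62550 (-2.58 ± 0.17), AT1G50040 (-2.53 ± 0.16), AT3G19680 (-2.46 ± 0.24), AT5G62280 (-2.45 ± 0.26), AT3G10020 (-2.40 ± 0.17), AT4G10910 (-2.35 ± 0.17) and MCCA (AT1G03090, -2.31 ± 0.17), a subunit of a leucine-degrading carboxylase. EXLA1 stood at -3.61 without the first and at -2.29 without the second array at 0.5 h. Set against 1 h instead of 0.5 h, several of these genes changed sides or lost their call at 24 h. AT2G15020 was then lower (-0.66) and AT3G15450 higher (1.02), AT3G19680 and AT4G10910 were at 0.11 and 0.44, WRKY22 at 0.09, AT5G42760 at 0.22 and AT5G62280 at -0.64, the last 5 not past the threshold. Smaller but still past it were AT1G02660 (-0.87), AKINBETA1 (-0.70), WES1 (-0.62) and AT2G27420 (0.58).

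Among gene groups in shoots at 24 h, 10 of 15 measured damage-induced loci rose and none fell, with a median of 0.93 (adjusted p = 8.59e-14, adjusted p = 0.0514 with an estimated correlation). Besides the 4 above they included AT3G42860 (1.54 ± 0.17), AT2G47680 (1.43 ± 0.18) and ATMND1 (AT4G29170, 0.93 ± 0.19), which is related to a yeast protein of meiotic recombination. This list was drawn from recall of published studies, some of which may have used these arrays, so it is not independent evidence of direction. Of the 4 measured core histone genes, all of histone H2B, 3 fell and 4 fell adjusted over the list alone, among them HTB11 (AT3G46030) at -0.61 ± 0.10 and HTB2 (AT5G22880) at -0.84 ± 0.23. The set fell (adjusted p = 0.028, adjusted p = 0.443 with an estimated correlation), but not without the second array at 0.5 h (adjusted p = 0.0711), the first at 24 h (adjusted p = 0.177) or the dimmest 30% of probe sets (adjusted p = 0.0603), in a range of 1.98e-05 to 0.443 over all alternatives. HTB2 lost its own call without either of those arrays (-1.32 to -0.36 with 1 array left out). Of 16 genes of mitosis and cytokinesis 4 fell, such as the phragmoplast kinesin gene KINESIN-12B (AT3G23670, -0.72 ± 0.16), and 12 did not pass. The other 3 lost their calls with 1 array left out, AUR1 (AT4G32830, -0.73, -1.02 to -0.44) without the first array at 0.5 h or at 24 h, 3xHMG-box2 (AT4G23800, -0.86) without the first at 24 h (-0.45), and 3xHMG-box1 (AT4G11080, -0.44, -0.58 to -0.31) without the first at 0.5 h or either at 24 h. That set's adjusted p of 0.022 became 0.759 with an estimated correlation, 0.159 without the first array at 0.5 h and 0.316 without the first at 24 h, from a lowest of 0.000214, and the call was lost under 4 of 21 alternatives.

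Genes of autophagy also moved in shoots at 24 h. Of 10 genes for ATG8 and ATG3, which build the autophagosome membrane, 4 rose and 1 fell, with APG8A (AT4G21980) at 0.82 ± 0.11 and ATG8H (AT3G06420) at 0.61 ± 0.14, and with ATG8E (AT2G45170) at -0.78 ± 0.19. The set rose (adjusted p = 0.0043, adjusted p = 0.458 with an estimated correlation, 0.121 without the first array at 24 h, lowest 4.08e-08; lost under 3 of 21 alternatives). ATG8E lost its call without the second array at 0.5 h or at 24 h (-1.08 to -0.48 with 1 array left out), and against 1 h it was higher (0.95). In the fixed list of senescence, cell death and autophagy, 3 of 5 rose and 1 fell, with the same counts adjusted over the list alone, and the set did not pass (adjusted p = 0.0714). Of 14 glutathione transferase genes, which detoxify reactive compounds, 6 rose, GSTU27 (AT3G43800) by 0.68 ± 0.13 (set: adjusted p = 0.00595, adjusted p = 0.0514 with an estimated correlation, 0.0714 without the dimmest 50% of probe sets, lowest 0.000515). Of 69 plastid genome genes 13 fell and 56 did not pass (median -0.42; adjusted p = 1.02e-06, adjusted p = 0.759 with an estimated correlation, 0.0632 without the second array at 0.5 h, lowest 1.13e-12). The second array at 24 h lay nearer to the root arrays, in which plastid genes were lower. Without it the set still passed, but rbcL (-0.997), psbD (-0.79) and atpF (-0.64) lost their calls, as they did without the second array at 0.5 h. With 1 array left out psbD was at -1.11 to -0.47, atpF at -0.82 to -0.47, and rbcL at -1.60 and -0.40 without the first and the second array at 0.5 h.

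The remaining fixed lists held few measured genes in shoots. Both flavonoid genes rose, also adjusted over the list alone. They were DFR (AT5G42800, 1.097 ± 0.27) and UF3GT (AT5G54060, 0.92 ± 0.21), enzymes of anthocyanin synthesis. DFR lost its call without the second array at 24 h (0.49), and UF3GT without that array or the second at 0.5 h, with values from 0.43 to 1.41. AT2G21640, listed for oxidative stress, rose by 1.65 ± 0.26, and the other measured gene of its list, GSTU25, stood at 0.73 ± 0.43 and did not pass. Of 5 auxin response genes 1 fell, WES1, or 3 adjusted over the list alone (set: adjusted p = 0.0714). STZ (AT1G27730), a zinc finger gene of rapid stress responses, rose by 1.35 ± 0.43, with 2.29 without the first array at 24 h and 0.41 without the second, and its call was also lost without either array at 0.5 h. Its set of 3 touch and wound genes had a median of -0.15 and a mean of 0.19 and did not pass (adjusted p = 0.768). Of 7 genes of crosslink repair and translesion synthesis none rose and 1 fell, both over all genes and adjusted over the list alone, AT1G48360 at -0.44 ± 0.11, a call lost without the first array at 0.5 h or at 24 h (values from -0.52 to -0.35; set: adjusted p = 0.793). Of 3 of homologous recombination 1 rose, ATMND1 (median -0.14, mean 0.17, adjusted p = 0.768), and none of 4 CDK inhibitors passed (adjusted p = 0.844). The DNA damage response list had 1 measured gene of 26, AT4G32700 (TEBICHI, a DNA polymerase), at -0.33 ± 0.19 (adjusted p = 0.254).

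**Figure D1:**
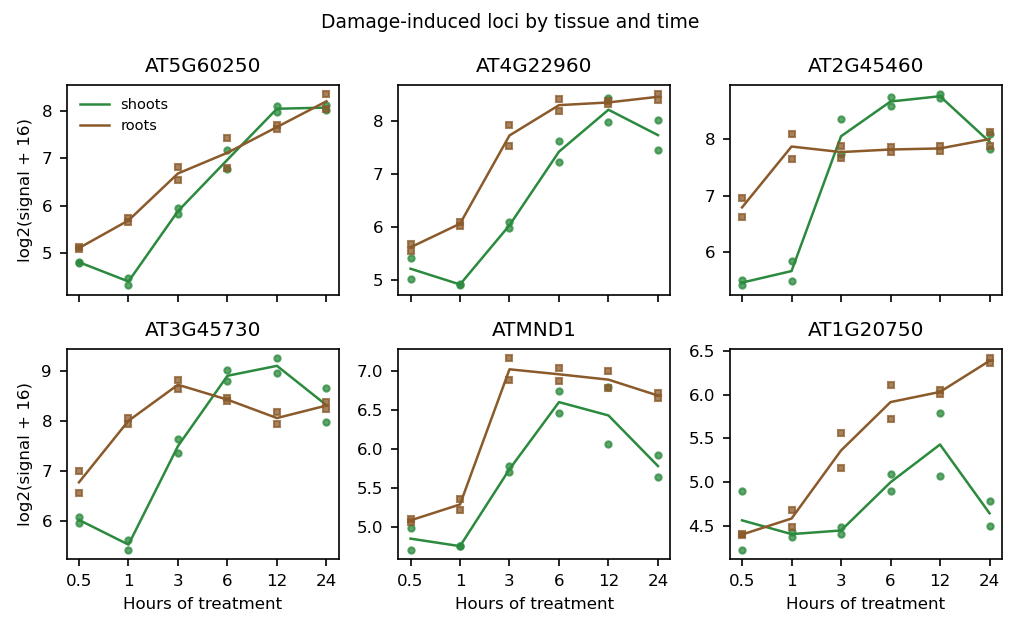
Log2(signal + 16) of 6 damage-induced loci over hours of treatment, with green circles for shoots, brown squares for roots, a point for each array and lines through the mean of 2 arrays. AT5G60250 climbed to 3.27 above 0.5 h in shoots and 3.102 in roots at 24 h, whereas AT1G20750 stood at 0.08 in shoots and 1.99 in roots.

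In roots, 24 h against 0.5 h, AT5G60250 led the ranked rises as it did in shoots, 8.58-fold (3.102 ± 0.17, adjusted p = 1.41e-08). AT4G22960 followed with a rise of 2.83 ± 0.19 (adjusted p = 1.01e-07). 3xHMG-box2, an HMG-box gene whose protein binds mitotic chromosomes, fell (-1.99 ± 0.19, adjusted p = 2.57e-06). The Aurora kinase genes AUR2 (AT2G25880) and AUR1 changed by -1.32 ± 0.13 and -1.03 ± 0.19, the topoisomerase II gene TOPII (AT3G23890) by -1.63 ± 0.23 and the histone genes HTB2 and HTB1 (AT1G07790) by -1.17 ± 0.23 and -0.83 ± 0.15. These calls and directions held with any 1 array left out. In the longer list of DNA replication TOPII alone of the 9 measured genes passed in roots, and the set did not pass (camera, adjusted p = 0.0704). TOPII was also called in shoots at 24 h.

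Altogether 2975 probe sets passed in roots at 24 h, 1456 higher and 1519 lower. The count was 1714 without the first and 1364 without the second array at 0.5 h, and 1368 without the first array at 24 h. The next largest rises were those of AT1G59265 (2.45 ± 0.21), a pseudogene in the annotation, AT1G26390 (2.39 ± 0.46), AT5G38910 (2.37 ± 0.38), AT2G18600 (2.24 ± 0.21), AT2G15220 (2.09 ± 0.36), AT1G20750 (1.99 ± 0.22), AT4G25330 (1.92 ± 0.22), AT2G18190 (1.90 ± 0.18), AT1G74770 (1.89 ± 0.16) and AT2G21640 (1.89 ± 0.26). Without the first and the second array at 24 h AT5G38910 rose by 3.04 and 1.70. Of the largest falls, those of AT5G19110 (-2.49 ± 0.23), AT5G28630 (-2.02 ± 0.38), AT3G61400 (-1.93 ± 0.28), the glutaredoxin gene GRX480 (AT1G28480, -1.90 ± 0.22) and AT1G26730 (-1.87 ± 0.18) held with any 1 array left out, as did that of 3xHMG-box2, but against 1 h GRX480 stood at -0.29 and AT1G76640, described below, at -0.80, and neither passed. At a pseudocount of 1 the rise of AT2G15220 did not pass (adjusted p = 0.086). The other falls leaned on the 0.5 h arrays. AT2G18210 stood at -2.48 ± 0.34, with -3.22 without the first and -1.75 without the second of them. By the same measure AT1G76640, a calmodulin-like gene, moved from -2.43 to -3.12 and -1.74, AT4G10270 from -1.87 to -2.49 and -1.26, and AT5G35940 from -1.86 to -2.51 and -1.21. The calls of AT4G10270, of AT3G10040 (-2.09, range -2.49 to -1.70) and of the calmodulin-like gene CML38 (AT1G76650, -2.70, range -3.25 to -2.15) were lost without the second array at 0.5 h and without the first at 24 h.

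Among gene groups in roots at 24 h, 13 of 15 damage-induced loci rose and none fell, with a median of 1.44 (adjusted p = 9.25e-22, adjusted p = 0.0208 with an estimated correlation). Of the list tests at 24 h in either tissue this was the only one to pass with an estimated correlation. As in shoots, the list was drawn from recall of studies that may have used these arrays, so it is not independent evidence of direction. Its members included AT2G18600, AT1G20750, ATMND1 (1.60 ± 0.19) and chr31 (AT1G05490), a chromatin remodelling gene, at 1.42 ± 0.24. A further probe set of chr31 stood at 0.25 (adjusted p = 0.305), and at a pseudocount of 1 its call was lost (adjusted p = 0.0658). All 3 measured genes of G2 and mitosis fell, AUR3 (AT2G45490) with AUR1 and AUR2, and so did all 4 core histone genes, with the same counts adjusted over the list alone. Both sets fell (adjusted p = 6.8e-05 and 6.56e-05, adjusted p = 0.0824 for both with an estimated correlation). AUR3, at -0.56 ± 0.16, lost its call without the first array at 0.5 h or either at 24 h, with values from -0.74 to -0.38, and HTB11, at -0.38 ± 0.10, lost its call whichever of the 4 arrays was left out (-0.44 to -0.32). In the longer list of mitosis and cytokinesis 8 of 16 fell and none rose, among them the spindle checkpoint gene BUB3.1 (AT3G19590, -0.84 ± 0.13) and 3xHMG-box1 (-0.87 ± 0.15), with an adjusted p of 4.46e-08 for the set (adjusted p = 0.139 with an estimated correlation).

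In the fixed list of senescence, cell death and autophagy 3 of 5 rose in roots, also adjusted over the list alone, but APG8A, ATG8H and AT4G18425 were each called by a small margin, and lost their calls in 3, 3 and 4 of the 4 fits with 1 array left out. APG8A stood at 0.42 ± 0.11 (0.34 to 0.50 with 1 array left out), ATG8H at 0.56 ± 0.14 (0.50 to 0.62) and AT4G18425 at 0.52 ± 0.16 (0.40 to 0.65). That set passed (adjusted p = 0.0351) but lost its call under 8 of 20 alternatives, among them those with an estimated correlation (adjusted p = 0.22) and without the second array at 0.5 h (adjusted p = 0.0704) or at 24 h (adjusted p = 0.0694), with 0.00674 as the lowest over all alternatives. ATG8B (AT4G04620) rose by 0.94 ± 0.13. AT4G14970, the FANCD2 gene of crosslink repair, rose by 0.81 ± 0.14 (adjusted p = 0.00106). It was 1 of 7 genes of its list to rise, or 1 of 2 adjusted over the list alone, and the set did not pass at 24 h (adjusted p = 0.137). FANCD2 is shared by the crosslink list and the longer list of DNA repair and recombination. ATMND1 is shared by that longer list, homologous recombination and the damage-induced loci listed from recall. These sets are therefore not separate evidence. In the longer list of DNA repair and recombination 2 of 22 rose, FANCD2 and ATMND1, and the set rose (adjusted p = 0.0401, adjusted p = 0.214 with an estimated correlation). The call of that set was lost under 5 of 20 alternatives, with 0.0785, 0.0553 and 0.0505 without the first array at 0.5 h and the first and the second at 24 h, and 0.00648 at the lowest. Homologous recombination had 1 of 3 genes higher, ATMND1, auxin response 1 of 5, IAA29 (AT4G32280, 0.98 ± 0.19), and CDK inhibitors 1 of 4, SIM (AT5G04470, 0.35 ± 0.11), with 1, 1 and 2 adjusted over the list alone and an adjusted p of 0.137 for each of these sets. IAA29 lost its call without the first array at 24 h (0.73), and SIM lost its call in 3 of the 4 fits with 1 array left out (0.24 to 0.45) and in most other settings, with 0.12 against 1 h. Neither flavonoid gene passed in roots, DFR standing at 0.23 ± 0.27 and UF3GT at 0.14 ± 0.21. In both tissues no measured gene passed at 24 h, nor adjusted over the list alone, in the lists of end joining (2 genes), excision and mismatch repair (1), replication (2), heat shock (2), photosynthesis (3) and root markers (3). The clock gene GI (AT1G22770) stood at -0.41 ± 0.18 in shoots and at 0.33 ± 0.18 in roots. As the only measured gene of its list, GI was lower in shoots only by its unadjusted p-value.

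Of the longer lists, 5 more passed in roots at 24 h, none of them with an estimated correlation. Of the 10 genes for ATG8 and ATG3 3 rose (adjusted p = 0.00588, adjusted p = 0.214 with an estimated correlation, 0.0553 without the first array at 24 h, lowest 0.00051). Of 10 genes of RNA polymerases I and III and rRNA processing 2 fell (adjusted p = 0.0117, adjusted p = 0.289 with an estimated correlation, 0.00428 at the lowest), and that call held with any 1 array left out. Of 5 cold-regulated genes 2 fell (adjusted p = 0.0401, adjusted p = 0.214 with an estimated correlation, 0.0669 and 0.0617 without the second array at 0.5 h and at 24 h, lowest 0.00755). Of 11 touch and wound genes CML38 alone fell (adjusted p = 0.0401, adjusted p = 0.419 with an estimated correlation). The call of the set was lost under 11 of 20 alternatives, with 0.406 without the second array at 0.5 h, 0.0774 and 0.0505 without the first and the second at 24 h, and 0.00143 at the lowest. Of 16 photosynthesis genes 1 rose (adjusted p = 0.0401, adjusted p = 0.578 with an estimated correlation). The call of the set was lost under 8 of 20 alternatives, with 0.376 and 0.0959 without the second array at 0.5 h and at 24 h, and 0.00218 at the lowest.

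**Figure D2:**
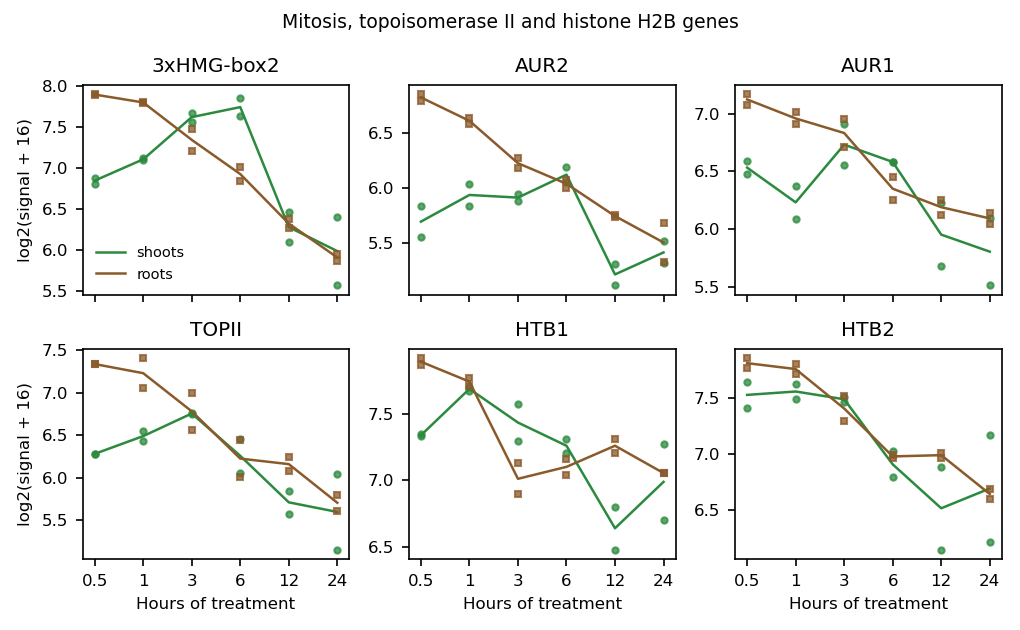
Log2(signal + 16) of 3xHMG-box2, AUR2, AUR1, TOPII, HTB1 and HTB2 over hours of treatment, with green circles for shoots, brown squares for roots, a point for each array and lines through the mean of 2 arrays. In roots all 6 were lower at 24 h than at 0.5 h, with 3xHMG-box2 at -1.99 and HTB1 at -0.83, and in shoots 3xHMG-box2 stood 0.90 above 0.5 h at 6 h.

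The tissues were next compared in their 24 h change. The energy kinase subunit gene AKINBETA1 fell less in roots than in shoots (difference, roots minus shoots, 1.49 ± 0.22, adjusted p = 0.000464; its root value of -0.75 lost its call without the second array at 0.5 h), and the auxin genes WES1 and IAA29 differed in the same direction (1.87 ± 0.26 and 1.48 ± 0.27). FANCD2 rose in roots beyond its shoot value of -0.18 (difference 0.99 ± 0.20, adjusted p = 0.00541). AUR2 and 3xHMG-box2 had the lower change in roots (-1.04 ± 0.19 and -1.13 ± 0.26), and AUR2 was not called in shoots. For AUR1 the difference of -0.30 ± 0.26 did not pass (adjusted p = 0.538). Of the damage-induced loci AT1G20750 and AT2G18600 rose more in roots (1.91 ± 0.31 and 1.55 ± 0.30) and AT2G45460 more in shoots (-1.29 ± 0.27), and the other 12 of the 15 did not pass, AT5G60250 with a difference of -0.17 ± 0.24. All of these calls held with any 1 array left out, but several rest on the 0.5 h arrays as the baseline. Set against 1 h, the differences of AKINBETA1 (-0.082), IAA29 (0.14), WES1 (0.81), AUR2 (-0.58), 3xHMG-box2 (-0.77) and AT2G18600 (0.72) no longer passed, while those of FANCD2, AT1G20750 and AT2G45460 did.

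In total 2135 probe sets differed between the tissues in the 24 h change, 1158 with the higher change in roots and 977 in shoots. The count was 1306 and 1341 without the first and the second root array at 0.5 h, and 1344 without the first root array at 24 h. Median centring turned the split from 54.2% to 40.5% higher in roots (860 against 1264 of 2124). Of 5 auxin response genes 2 had the higher change in roots, or 3 adjusted over the list alone, and the set passed (adjusted p = 0.0225, adjusted p = 0.315 with an estimated correlation, 0.099 without the first root array at 24 h, lowest 0.00199; lost under 3 of 23 alternatives). For G2 and mitosis 1 of 3 genes passed over all genes and adjusted over the list alone, AUR2 (set: adjusted p = 0.0567), and for core histones none of 4 (set: adjusted p = 0.286). In crosslink repair 1 of 7 passed, also adjusted over the list alone (set: adjusted p = 0.159). Of the longer lists, mitosis and cytokinesis passed, with 2 of 16 genes lower in roots (adjusted p = 0.0258, adjusted p = 0.787 with an estimated correlation). The call of the set was lost under 12 of 24 alternatives, with 0.242, 0.222, 0.0628 and 0.0819 without the second shoot array at 0.5 h, the second at 24 h, the first root array at 0.5 h and the first at 24 h, and 0.00186 at the lowest. The plastid genome passed too, with 2 of 69 higher and 1 lower (adjusted p = 0.0258, adjusted p = 0.787 with an estimated correlation). The call of that set was lost under 8 of 24 alternatives, with 0.608, 0.594, 0.0603 and 0.24 without the second shoot array at 0.5 h, the second at 24 h, the first root array at 0.5 h and the second at 24 h, and 8.66e-08 at the lowest. The calls at 24 h overlapped between the tissues. These share no arrays, but the spread of each probe set was estimated over all 24 arrays. The calls are therefore not independent, and the counts for independent lists are only a rough guide. Of 22746 probe sets 480 were higher in both, where independent lists would give 128.9, and 420 were lower in both against 153.7. Another 50 were higher in shoots and lower in roots, where 134.5 would be expected, and 42 the reverse against 147.3.

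Each later time was compared with the same 0.5 h arrays, and the genes followed at times other than 24 h were chosen after their values were seen. Most damage-induced loci rose early in roots. Already at 3 h 12 of 15 had risen there, ATMND1 by 1.93 ± 0.19, AT4G22960 by 2.103 ± 0.19 and AT5G60250 by 1.58 ± 0.17, and at 6, 12 and 24 h 12, 13 and 13 had. Each of these set tests passed with an estimated correlation too (adjusted p = 0.0174, 0.0149, 0.016 and 0.0208). In shoots 9 had risen at 3 h, 10 at 6 h, 12 at 12 h and 10 at 24 h, and AT5G60250 went from 1.08 ± 0.17 at 3 h to 3.24 ± 0.17 at 12 h. The medians in shoots were 0.82, 1.75, 1.58 and 0.93, and the test passed with an estimated correlation at 6 h (adjusted p = 0.0454) but not at 3 or 12 h (adjusted p = 0.215 and 0.0905). At 1 h 1 locus had risen in shoots and 4 in roots. At all times the limit given above holds, that the list was recalled from studies that may have used these arrays.

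The longer list of DNA repair and recombination also passed in roots before 24 h. It shares ATMND1 and FANCD2 with other lists, as given above, so those sets are not separate evidence. In it 4 of 22 had risen at 6 h and 4 at 12 h, ATMND1 by 1.87 ± 0.19 and 1.80 ± 0.19 (sets: adjusted p = 0.00807 and 0.00681, adjusted p = 0.125 and 0.155 with an estimated correlation). The set at 12 h passed with any 1 array left out, and that at 6 h did not without the second array at 6 h (adjusted p = 0.125, lowest 0.00106). Of 7 genes of crosslink repair 2 had risen at 6 h and 1 at 12 h, with the same counts adjusted over the list alone (sets: adjusted p = 0.0126 and 0.0177, adjusted p = 0.0542 and 0.07 with an estimated correlation). These sets did not pass without the second array at 6 h (adjusted p = 0.115, lowest 0.00103; lost under 3 of 19 alternatives), or at 12 h without the first array at 0.5 h or the second at 12 h (adjusted p = 0.0531 and 0.0656, lowest 0.000858; lost under 4 of 19 alternatives). Of 3 genes of homologous recombination ATMND1 alone had risen at 12 h, also adjusted over the list alone (set: adjusted p = 0.0464, adjusted p = 0.116 with an estimated correlation). The call of the set was lost under 11 of 19 alternatives, with 0.0761 and 0.0912 without the first array at 0.5 h and the second at 12 h, and 0.000858 at the lowest.

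Genes of cell division were followed over the same times. In roots 1 of 16 genes of mitosis and cytokinesis had fallen at 3 h, AUR2 at -0.60 ± 0.13, which lost its call whichever of the 4 arrays was left out (-0.65 to -0.55). The set already passed there (adjusted p = 0.00786, adjusted p = 0.469 with an estimated correlation, 0.0904 without the first array at 0.5 h, lowest 0.00254; lost under 4 of 20 alternatives). Of these genes 6 had fallen at 6 h, 5 at 12 h and 8 at 24 h, with AUR2 at -0.79 ± 0.13 and -1.08 ± 0.13 at 6 and 12 h and 3xHMG-box2 at -0.97 ± 0.19 and -1.58 ± 0.19. The set also fell at 6 and 12 h (adjusted p = 1.75e-07 and 1.92e-07, adjusted p = 0.125 and 0.155 with an estimated correlation). Of the 4 H2B histone genes HTB1 alone had fallen in roots at 3 h, at -0.88 ± 0.15, and 3 had when adjusted over the list alone (set: adjusted p = 0.000367, adjusted p = 0.127 with an estimated correlation). All 4 had fallen there at 6 and 12 h, also adjusted over the list alone, with HTB1 at -0.79 ± 0.15 at 6 h (sets: adjusted p = 3.09e-06 and 0.000175, adjusted p = 0.0542 and 0.07 with an estimated correlation). In roots HTB2 lost its call at 6 h (-0.84) and 12 h (-0.82) whichever of the 4 arrays was left out, with values from -0.88 to -0.79 and from -0.86 to -0.78, and HTB1 at 12 h (-0.63, -0.68 to -0.58) in 3 of 4 fits. In shoots the mitosis genes moved both ways. At 3 h 2 of 16 had risen, and the set rose (adjusted p = 0.00949, adjusted p = 0.537 with an estimated correlation, 0.161 without the second array at 0.5 h, lowest 0.00229; lost under 6 of 20 alternatives). At 6 h 3 had risen, 3xHMG-box2 by 0.90 ± 0.19, and the set did not pass (adjusted p = 0.167). At 12 h 8 had fallen, and again the set did not pass (adjusted p = 0.0517). Of these 8, AUR1 (-0.58, -0.85 to -0.31) and 3xHMG-box2 (-0.57, -0.75 to -0.39) each lost their call without either array at 0.5 h or the first at 12 h. All 4 histone genes had fallen in shoots at 12 h, with HTB1 at -0.70 ± 0.15 (set: adjusted p = 0.00651, adjusted p = 0.359 with an estimated correlation).

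**Figure D3:**
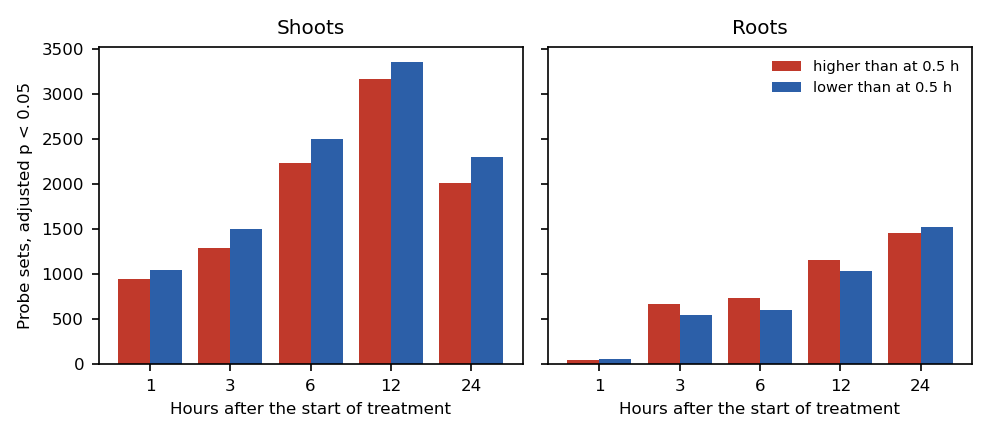
Number of probe sets with an adjusted p below 0.05 against 0.5 h at each later time, in shoots and in roots, with red bars for higher and blue bars for lower. In shoots the bars were largest at 12 h (3174 higher, 3357 lower) and in roots at 24 h (1456 higher, 1519 lower).

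Shoots had already changed at 1 h. Between 0.5 h and 1 h AT3G15450 changed by -3.62 ± 0.18, AT1G02660 by -2.55 ± 0.18, WRKY22 by -1.77 ± 0.17 and AKINBETA1 by -1.53 ± 0.15, while AT2G15020 was higher by 3.68 ± 0.16 and AT2G27420 by 2.55 ± 0.16. The fall of AT3G15450 was deepest at 12 h (-4.59 ± 0.18), as was that of AKINBETA1 (-2.82 ± 0.15). In roots none of these 6 genes passed at 1 h, with AT3G15450 at -0.13 and AT2G15020 at 0.00, and the difference between the tissues at 1 h was not tested. In all 1992 probe sets passed in shoots at 1 h, 947 higher and 1045 lower, against 107 in roots, 47 higher and 60 lower.

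The counts then grew to 2791, 4740 and 6531 in shoots at 3, 6 and 12 h, and to 1219, 1329 and 2197 in roots. A change at any time was called for 9184 probe sets in shoots and 3708 in roots. Several counts fell by over 1.5 times when 1 array was left out. In shoots at 1 h, 1197 remained without the first array at 0.5 h, 1175 without the first at 1 h and 1229 without the second at 1 h. At 3 h the shoot count was 1741 without the first array at 0.5 h and 1601 without the second at 3 h, and at 6 h 3154 without the first array at 6 h. In roots at 1 h it was 25 without the second array at 0.5 h, 40 without the first at 1 h and 44 without the second. At 3 h the root count was 645 and 675 without the first and the second array at 0.5 h, and 750 and 586 without the first and the second at 3 h. The counts of 775 and 684 at 6 h and of 1346 and 1099 at 12 h were those without the first and the second root array at 0.5 h, and 1229 and 1385 those without the first and the second at 12 h. Median centring turned the split at 6 h in roots from 54.9% to 42.6% higher (562 higher and 756 lower of 1318).

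**Figure D4:**
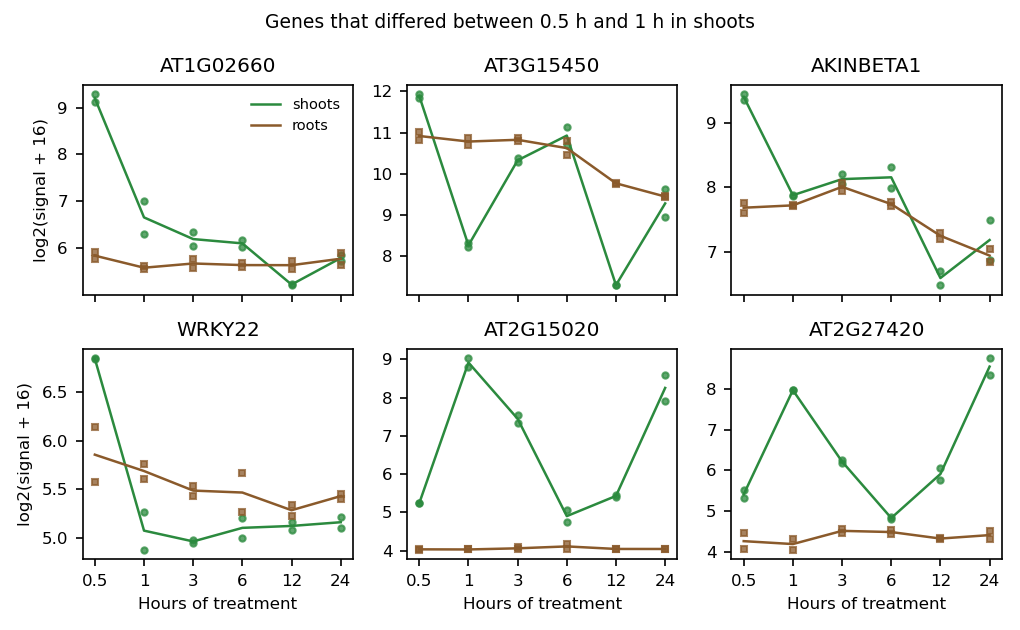
Log2(signal + 16) of AT1G02660, AT3G15450, AKINBETA1, WRKY22, AT2G15020 and AT2G27420 over hours of treatment, with green circles for shoots, brown squares for roots, a point for each array and lines through the mean of 2 arrays. In shoots AT3G15450 dropped between 0.5 and 1 h (-3.62) and AT2G15020 rose (3.68), and in roots they moved by -0.13 and 0.00.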

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

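The tests of this part were set before the values they rest on were seen, except the fit without both shoot arrays that lay nearest to the roots, which was chosen only after the result was seen.

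The 24 h change differed between roots and shoots for 2135 probe sets, and the 16 genes below are the largest such differences by the naming rule, given as roots minus shoots. Higher in roots were AT1G02660 (3.35), AT5G62280 (3.11), AT3G62550 (2.57), AT2G15960 (2.51), AT4G10910 (2.45), AT1G59265 (2.41), AT2G29300 (2.33) and AT5G38910 (2.33). Of these, the first 5 and AT2G29300 fell in shoots and AT1G59265 and AT5G38910 rose in roots. The root value of AT2G29300 was 0.34, beside -1.995 in shoots. Lower in roots were AT2G18210 (-3.01), AT2G15020 (-3.002), AT2G27420 (-2.98), the peroxidase gene AT5G64120 (-2.86), TBL26 (-2.58), AT5G19110 (-2.56), AT1G19960 (-2.52) and AT1G76640 (-2.43). Left-out arrays moved 4 of these by over 1.5 times as folds. AT5G38910 was at 2.99 and 1.66 without the first and the second root array at 24 h, and its call was lost without the second root array at 0.5 h or at 24 h. AT2G18210 was at -3.75 and -2.28 and AT1G76640 at -3.12 and -1.74 without the first and the second root array at 0.5 h. AT5G64120 was at -3.45 and -2.27 without the first and the second shoot array at 24 h, and its call was lost without the second of these, the first shoot array at 0.5 h, the second root array at 0.5 h or the first root array at 24 h. Set against 1 h, the differences of AT4G10910 (-0.20), AT2G15020 (0.68), AT2G29300 (0.06), AT3G62550 (0.54), AT2G27420 (-0.36), AT1G76640 (-0.80), AT5G62280 (1.23) and AT5G38910 (1.53) no longer passed.

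The first shoot array at 12 h and the second at 24 h lay nearer to the root arrays than the other shoot arrays did. Root RNA in these samples could raise root-enriched transcripts, and 70.7% and 67.9% of 393 root-enriched probe sets were brighter than on the partner array, against 40.8% to 50.1% in the other 4 pairs. Those shares lie between the bounds set in advance for and against this explanation. The bound in its favour also asked for at least 18 of the 20 brightest root-enriched probe sets in both arrays, and 13 were brighter at 12 h and 18 at 24 h, against 10 to 13 in the other pairs. The median implied root share was 0.59% at 12 h (quartiles -0.07% and 1.97%) and 0.70% at 24 h (quartiles -0.21% and 2.19%). Scaling might raise such transcripts as well, but probe sets of equal level in both tissues were brighter in 56.0% and 45.0%, which left gaps of 14.7 points at 12 h, between the bounds of 10 and 20, and 22.9 points at 24 h, above them, where the bound had been set for both arrays together. Both sources, and a difference between plants, stay open.

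Shoots at 0.5 h differed from those at 1 h in 1992 probe sets, among them AT3G15450 and AKINBETA1. Over all 1992 the median change was 0.68 and 0.61 against each 0.5 h array, the smaller 89.6% of the larger. That decides nothing about a single deviating 0.5 h array, as a call from the mean of both favours probe sets on which they agree. Such an array as the only source is argued against by the fits without it, with 1197 calls without the first and 2295 without the second, of which 1066 and 1488 were also called in the same direction with all arrays. A part from the first array stays open. A state of the 0.5 h shoots that was over by 1 h could enter every comparison with 0.5 h, and 47.6% of the probe sets called at 24 h (2056 of 4315) were also called in the same direction against 1 h, where a share under 50% had been set for this explanation. That share does not decide it, because no value was set for the calls lost to the threshold alone, both comparisons share the 24 h arrays, and roots, with 107 changes at 1 h, gave 57.6% (1713 of 2975). In shoots 152 probe sets were called in opposite directions against 0.5 h and 1 h, and in roots 0. The further touch and wound list, of which WRKY22 is a member, passed as a set in shoots at 1 h (adjusted p = 0.0189, adjusted p = 0.896 with an estimated correlation). It also passed at 3 h (adjusted p = 0.0092), but not with 3 h set against 1 h (adjusted p = 0.909). These set tests do not tell handling from the other sources. Whether a passing state of the 0.5 h shoots, handling, light or a fast response to the drugs lay behind the early change stays open, as untreated plants were not analysed here.

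The number of changed probe sets in shoots was highest at 12 h, 6531, and lower at 24 h, 4315. The hour of day may contribute, because 12 h fell 15 h after lights on. Over the probe sets called at 12 h the median ratio of the 24 h change to the 12 h change was 0.52 in shoots and 0.88 in roots, with both times set against the same 0.5 h arrays. The shoot value lies between the bounds of 0.25 and 0.75 set in advance, and 41.4% of the 12 h calls in shoots were also called at 24 h. A passing response to the drugs would give the same, so both stay open.

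Shoots and roots differed in most probe sets. Of 100 splits of the arrays only 1, the real one, called as many (16361 probe sets in a fit without times, highest other 1). The other splits mix shoots with roots, which puts the tissue difference into the spread and leaves few calls possible. Their low counts therefore add nothing to the tissue markers above, and no conclusion about chance is drawn from them.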

How the results depend on the processing

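Most tests in this part were planned. The fit without both shoot arrays that lay nearest to the roots and the 18 further lists were chosen only after the data were seen. So were some gene values counted below, among them those of the CYP71B genes and of genes followed at times other than 24 h. Of 175 counts under other settings 165 stayed within 1.5 times, as did 71 of 96 with 1 array left out. Of 3390 values of named genes under other settings 3185 kept their call and direction, 191 lost the call and 14 changed sign, and of 1272 with 1 array left out 1082 kept both and 190 lost the call. Of 2186 list tests under other settings 1954 stayed, 190 lost the call, 40 gained it and 2 changed sign, and of 824 with 1 array left out 735 stayed, 74 lost it, 13 gained it and 2 changed sign. Lists that passed neither in the main fit nor in the alternative are among those that stayed, so these shares do not measure how firm the calls were. With an estimated correlation the rise of the damage-induced loci, listed from recall, held in roots from 3 to 24 h and in shoots at 6 h. The rise of the cold genes in shoots at 6 h held too. Signal over background limits dim probe sets, as detection calls were not used here.

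With 1 array left out, where a lone array is assumed to vary like other groups, the counts in shoots were 1175 to 2295 at 1 h, 1601 to 2671 at 3 h, 3154 to 4354 at 6 h, 4925 to 6094 at 12 h, 3002 to 3628 at 24 h and 8338 to 9478 over all times. In roots they were 25 to 92, 586 to 750, 684 to 991, 1099 to 1385, 1364 to 2208 and 2742 to 3877. The tissue difference at 24 h gave 1306 to 2320 and shoots against roots 17227 to 17494. The number of fixed lists that passed was 0 to 1 in shoots at 24 h, 2 to 3 in roots and 0 to 4 for the difference. The touch and wound list of the further lists changed sign in roots at 1 h without the second array at 0.5 h (adjusted p = 0.934 against 0.0433, lowest 2.77e-05), and the plastid genome list without the second at 1 h (adjusted p = 0.558 against 0.00295, lowest 1.28e-11).

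In roots at 1 h, where 107 passed, 46 passed at a pseudocount of 1, 166 at 64, 66 without the dimmest 50% and 65 with roots fitted alone, and the share of higher calls moved from 43.9% to 65.2% at a pseudocount of 1, 62.1% and 54.6% without the dimmest 50% and 30%, 56.9% with roots alone and 33.7% without the first array at 0.5 h. Without the dimmest 50%, 10189 differed between shoots and roots because fewer were tested. Shoots alone gave 1243 at 1 h and 1805 at 3 h, and against 1 h roots gave 652, 658 and 1431 at 3, 6 and 12 h. Apart from the number tested, the cause was not tested.

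Against 1 h, these signs changed in shoots at 24 h: AT2G15020 -0.66, AT3G15450 1.02, AT3G19680 0.11, AT4G10910 0.44, ATG8E 0.95 (0.085 against the mean of 0.5 and 1 h), WRKY22 0.0857, UGT73B1 0.15, ATCRT1 0.15, AT2G29300 0.19 and CYP71B26 -0.46. In the tissue difference AKINBETA1 became -0.082, AT4G10910 -0.20 and AT2G15020 0.68. The further touch and wound list in shoots at 24 h (adjusted p = 0.0159 against 0.967) and the damage-induced loci in the difference (adjusted p = 0.0383 against 0.427) changed sign too, and the cause was not tested.

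The number of fixed lists that passed in shoots at 24 h, 1, was 3 at a pseudocount of 1, with shoots alone and against 1 h, 2 against the mean baseline, 0 without the dimmest 30% and with an estimated correlation, and 4 with fry. In roots 3 became 1 without the dimmest 50%, 0 with an estimated correlation and 5 with fry. In the difference 1 became 2 at a pseudocount of 64, with either quantile normalization and against 1 h, 3 against the mean baseline and with fry, and 0 without the dimmest 50% and with an estimated correlation. The cause was not tested.

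With a replicate block within each tissue 4117 passed in shoots at 24 h, 2806 in roots and 1940 in the difference, and no count moved by over 1.5 times. Residuals of arrays with the same number correlated at -0.191 to 0.199 over 66 pairs of groups, 6 of them over 0.1, so no strong pairing by number was seen. For shoots and roots of the same time r was 0.0376, -0.0194, -0.0411, -0.0887, 0.105 and 0.135 at 0.5, 1, 3, 6, 12 and 24 h. A weak pairing of shoots and roots, which would bear on the tissue difference at 24 h, cannot be excluded by these values. Without both shoot arrays nearest to the roots 5286 passed in shoots at 12 h, 3518 at 24 h and 1696 in the difference.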

Other observations

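Cold-regulated genes rose together in shoots at 6 h, where all 5 measured rose against 0.5 h. These genes, the CYP71B genes and the ALDH genes below, and the tests of symbol families, were chosen only after the result was seen. COR15B (AT2G42530) rose by 4.15 ± 0.37, COR15A (AT2G42540) by 2.65 ± 0.30 and COR27 (AT5G42900) by 2.85 ± 0.15, and the dehydrin genes LTI30 (AT3G50970) and COR47 (AT1G20440) by 1.06 ± 0.13 and 1.04 ± 0.18. The set passed with an estimated correlation too (adjusted p = 3.63e-09, adjusted p = 0.00706 with an estimated correlation). At 12 h COR27 was still up by 3.13 ± 0.15 and COR15B by 2.097 ± 0.37, the latter at 2.70 and 1.49 without the first and the second array at 12 h, and at 24 h neither passed (-0.01 and -0.17). At 12 h 4 of the 5 had risen. In roots at 6 h 1 of 5 rose, COR27 by 1.68 ± 0.15. GI, the clock gene, rose by 2.83 ± 0.18 in shoots and 0.93 ± 0.18 in roots at 6 h, the latter a call lost without the first root array at 0.5 h. The tissue differences at 6 h were not tested, and length of treatment and hour of day changed together. Of 9 xyloglucan endotransglucosylase genes, which remodel cell walls, 4 fell in shoots at 6 h, such as XTH32 (AT2G36870, -1.05) and XTH19 (AT4G30290, -1.08, a call lost without the second array at 0.5 h), with an adjusted p of 0.00804 for the set (adjusted p = 0.0984 with an estimated correlation, 0.143 without the second array at 0.5 h, lowest 7.01e-05).

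Of 47 UDP-glucosyltransferase genes at 24 h 7 rose and 6 fell in shoots and 9 rose and 3 fell in roots, and 12 had the higher and 6 the lower change in roots, so the genes moved both ways and no set passed (adjusted p = 0.768, 0.0589 and 0.566). UGT78D1 (AT1G30530), a flavonol glycosyltransferase, rose in shoots by 1.19 ± 0.19 (0.57 and not past the threshold against 1 h), and UGT72E1 (AT3G50740) and UGT72E2 (AT5G66690), which glucosylate monolignols, rose in roots by 1.57 ± 0.23 and 1.36 ± 0.19 (difference from shoots for UGT72E2 1.43 ± 0.27, or 0.73 and not past the threshold against 1 h). The glutathione transferase set did not pass in roots (adjusted p = 0.0589), but GSTU22 (AT1G78340) rose in roots by 1.23 ± 0.18 (0.51 and not past the threshold against 1 h) and ATGSTF13 (AT3G62760) changed by -1.56 ± 0.18. The dehydrin gene COR47, of the abscisic acid list, was lower in both tissues (-0.67 ± 0.18 in shoots, -0.88 ± 0.18 in roots), calls lost in each tissue without the second array at 0.5 h or at 24 h (-0.78 to -0.56 and -1.101 to -0.65). Among 26 measured genes with symbols that begin with CYP, a prefix of cytochrome P450 genes and of some cyclophilins, 8 rose in shoots at 24 h and none fell (adjusted p = 0.0142, adjusted p = 0.0737 with an estimated correlation). Under the baseline of 1 h CYP71B26 turned from 0.93 to -0.46. All 8 were of the P450 subfamily CYP71B, such as CYP71B24 (1.07) and CYP71B36 (0.86), while CYP71B22 stood at -0.96 (adjusted p = 0.0819). With 1 array left out 4 of the 8 lost their call. They were CYP71B23 (1.097) without the second array at 24 h (0.76), CYP71B5 (0.93, 0.73 to 1.14) and CYP71B35 (0.64, 0.46 to 0.82) without the first at 0.5 h or at 24 h, and CYP71B6 (0.76, 0.61 to 0.90) without the second at either time. In roots 4 of the 26 rose (adjusted p = 0.0856), and none passed in the difference (adjusted p = 0.568). Of the 43 families NRPB, of RNA polymerase II subunits, also passed in shoots at 24 h, with 2 of 6 genes higher (adjusted p = 0.0292, adjusted p = 0.517 with an estimated correlation). Of 8 aldehyde dehydrogenase genes 6 rose in shoots at 6 h (adjusted p = 0.00901, adjusted p = 0.165 with an estimated correlation).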
